A study of Rattus norvegicus with 28 samples.

How the data were processed

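RNA of adult rat cardiomyocytes was sequenced as 75 bp single-end reads in 3 null adenovirus and 3 shDesmin adenovirus libraries, and Lamin B ChIP with matched inputs was sequenced from scrambled and shDesmin cells as 22 libraries, 10 of them re-runs, per the labels. Groups were taken from the labels only. Per-sample ChIP signal was not used here.

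The deposited RNA table holds log2 values that the authors scaled per library, and the submitters' processing notes name Trimmomatic 0.32, STAR 2.6.0c, featureCounts, edgeR and limma without saying which step used which. Checked on the values, 2 raised to each value is a step fixed per library times a whole number plus 0.5, and 100% of values of every library gave a whole read count within 0.001. The values are therefore log2 CPM of reads plus 0.5 over an effective library size, plus a constant shared by all libraries. That constant was subtracted, so levels here are log2 CPM. The recovered reads summed to 9205608, 8724543 and 10908458 in the null libraries and to 9615721, 9168307 and 9817421 in the shDesmin libraries, over the listed genes only. A count of 3 reads, the limit that 0 reads allows, equals 0.23 to 0.45 CPM, and such limits cover counting error only. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom from 4.94 to 36.7), so none is a re-run of another library, which does not show that they are separate cultures. Each counted as 1 sample. Same-numbered null and shDesmin libraries had correlations of 0.13, -0.07 and -0.17 between their deviations from group means, so the numbers do not pair them.

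The authors' deposited table of differential expression gives a signed fold (ratio) score, a moderated t score and p-values with their adjusted values, per the file headers, and was used only for comparison. The LAD list holds interval starts and ends on rn6 without a score, made from 3 pooled ChIP replicates with inputs, per the series' design text. BWA, Picard, SAMtools, deepTools and bedtools are named in the submitters' processing notes. Starts are multiples of 600 bp, and no domain or gap is shorter than 50.4 kilobases. Gene positions come from the RNA table, which uses the same build, and carry no strand.

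Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2 CPM, for genes above 0 log2 CPM in at least 3 of 6 libraries, with group as the only term, and the Benjamini-Hochberg adjustment with a threshold of 0.05, two-sided. This left 11033 of 11383 genes. With log2(CPM) values from reads plus 0.5, folds of genes with few reads are understated. The 30 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists covered sarcomere, intercalated disc and costamere, intermediate filaments, microtubules, lamina and LINC complex, p53 targets, DNA repair, cell cycle, stress and immune programmes, energy metabolism, calcium handling, matrix, transcription factors, neuronal genes, cholesterol synthesis, proteostasis and markers of other cell types. Lists with at least 4 tested members were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. Genes named are Des, the 10 largest rises and the 10 largest falls by log2 fold among called genes with mean log2 CPM of at least 3, a symbol that is not an ID and no overlap between groups, up to 3 members of each list with the smallest adjusted p, and up to 5 called genes in LADs with the largest change at that level.

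A gene was placed in a LAD when at least 50% of its length was covered. Differences of medians were tested with 10000 rotations of the LADs along each chromosome, whose end was taken as the last gene or LAD, calls were compared with Fisher's exact test, which treats genes as independent, and 10000 draws of outside genes were matched on 10 bins of mean log2 CPM, with the same reservation. The share of all annotated genes that was tested was not computed, because no annotation of this build was used here. Calculations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots in matplotlib 3.10.9.

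The limma step was tested on simulated data. For shDesmin RNA against null RNA over 11033 genes, 88 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2 were recovered, and 6 unchanged genes were called. Only 200 genes were changed, with the same dispersion of 0.01 for every gene, independent genes and known library sizes. The simulation therefore does not test the scaling between libraries or a change as broad as the observed one. For LADs over 11000 genes, a shift of 0.5 was called in 20 of 20 simulated sets, while without a shift the rotation called 46 of 100 sets and shifting LAD genes in gene order 3 of 100.

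Alternatives covered the filter, the pseudocount, median centring, quantile normalization, the variance model, library weights, the replicate block, leaving out each library, the authors' deposited table and the definition of a gene in a LAD. Chosen after the data were seen were scaling by library totals with or without mitochondrial genes, voom on recovered reads, the intermediate filament list without Des (camera and fry), and the shift of LAD genes in gene order, alone and under the other alternatives used for LADs except matching.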

Results

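Adult rat cardiomyocytes, the contractile cells of the heart, were isolated from animals aged 6 to 8 months, cultured for 48 hours and infected with adenovirus, and 28 samples were recorded. Of these, 22 were Lamin B chromatin immunoprecipitation (ChIP) or input libraries from cells given an shRNA against desmin (shDesmin) or a scrambled shRNA. The other 6 were RNA libraries, 3 from cells given a null adenovirus and 3 from cells given the shDesmin adenovirus. Desmin is the main intermediate filament protein of heart muscle and links the sarcomere lattice to the cell membrane and the nucleus. The study's title places desmin filaments against microtubules in the upkeep of nuclear shape, so the RNA comparison asks which transcripts differ when desmin is depleted, and the ChIP list asks which genes lie at the nuclear lamina. The RNA values were log2 CPM, read counts scaled to a common library size, of 11383 genes, and the ChIP result was a list of lamina-associated domains (LADs) in control cells only. The RNA libraries held between 8724543 and 10908458 reads over the listed genes. In the labels the RNA controls are null virus rather than scrambled shRNA, so this comparison also holds the presence of an shRNA. Nothing in the labels says whether the 3 RNA libraries of a group came from separate animals or cultures, and the p-values then measure only the spread between these libraries.

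The desmin transcript was depleted in all 3 shDesmin RNA libraries. Des (ENSRNOG00000019810, rn6 chromosome 9, 82556573 to 82564294) stood at 12.57 ± 0.03 log2 CPM (SD, n = 3) in null RNA and at 9.18 ± 0.12 (SD, n = 3) in shDesmin RNA, a 10.5-fold lower level (log2 change -3.39, SE 0.10, limma adjusted p = 7.3e-09). About 9.54% of the null level remained, and Des went from rank 10 to rank 198 of the 11033 genes tested. The reads behind these values were 79455, 66101 and 79168 for Des in the null libraries and 4406, 3752 and 4921 in the shDesmin libraries. An exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest value this design allows. The authors' deposited table lists Des at a signed fold of -10.48.

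**Figure D1:**
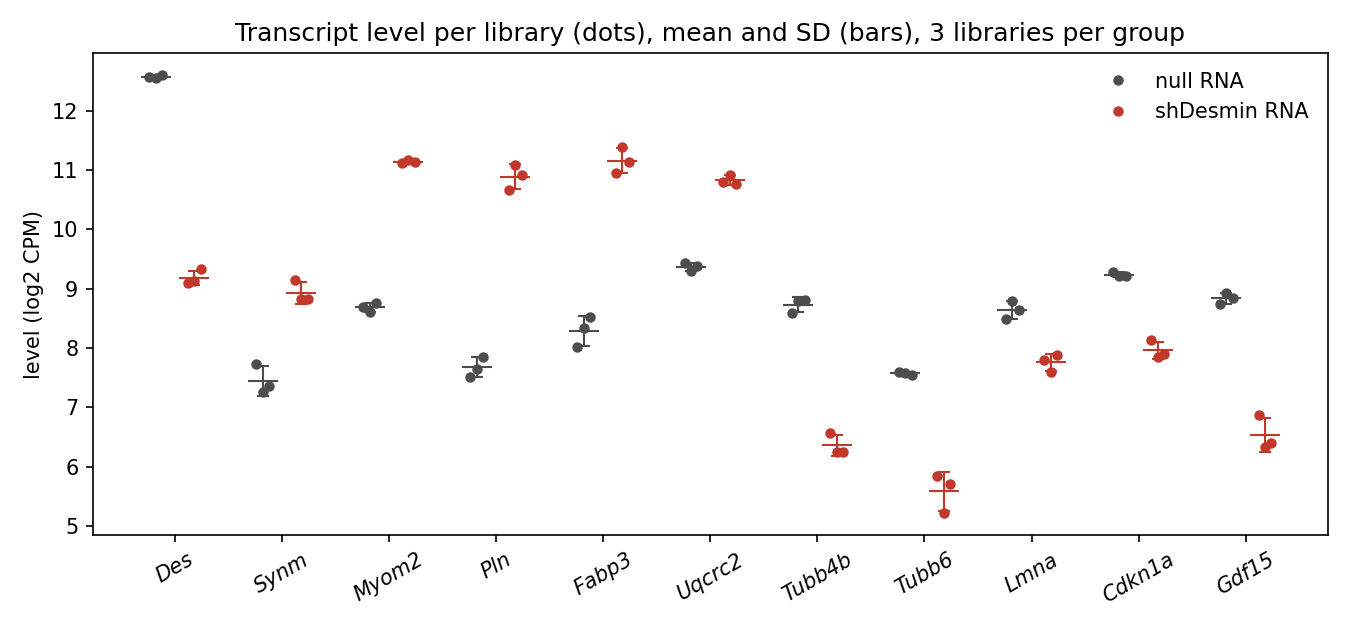
Level of 11 transcripts in log2 CPM (vertical axis) in each null RNA library (grey dots) and each shDesmin RNA library (red dots), with the mean and SD of each group as bars, n = 3. Des fell from 12.57 to 9.18, while Myom2, Pln and Fabp3 rose and Tubb4b, Tubb6 and Gdf15 fell, with no overlap between groups for any gene shown.

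More of the transcriptome differed than did not. Of 11033 genes tested, 3036 were higher and 3459 lower in shDesmin RNA (limma, adjusted p under 0.05), and 1169 and 1581 of these changed at least 2-fold. The largest rises among well-measured genes with a symbol were in S1pr3, a sphingosine 1-phosphate receptor (3.23 ± 0.16 to 6.97 ± 0.14 log2 CPM, SD, n = 3, 13.4-fold, adjusted p = 8.1e-09), Tecrl (12.2-fold), the chemokine gene Cxcl10 (11.7-fold), Pln, which encodes the inhibitor of the sarcoplasmic reticulum calcium pump (9.28-fold), and Nmrk2, a nicotinamide riboside kinase (8.62-fold). Sh3kbp1 (7.50-fold), Wfdc1 (7.46-fold), the fatty acid binding protein gene Fabp3 (7.30-fold), the junctional adhesion gene Jam2 (7.13-fold) and the lipoprotein lipase gene Lpl (6.90-fold) completed the 10 largest rises. The largest falls were in Klhl30 (5.49 ± 0.12 to 1.54 ± 0.13 log2 CPM, SD, n = 3, 15.5-fold, adjusted p = 1.9e-08), Lexm (10.6-fold), Htatip2 (10.5-fold) and Des itself. Brf2, a subunit of an RNA polymerase III initiation factor, fell 7.71-fold, Pigy 7.64-fold, Cnksr1 7.26-fold, Isg20 7.18-fold, the transcriptional repressor gene Bhlhe40 7.06-fold and Bcl2l1, which encodes an inhibitor of apoptosis, 7.03-fold. The groups did not overlap at all for 64.9% of tested genes, where chance gives 10% for 3 libraries against 3. In the table the authors deposited, the genes higher numbered 2992 and those lower 3515 at the same threshold, and all 6298 genes called both there and here had the same direction.

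The split into higher and lower genes depended on how libraries were scaled. Scale factors implied by the deposited values ran from 1.17 to 1.42 in the null libraries and from 0.73 to 0.83 in the shDesmin libraries, so they differ between groups. With each library centred on its median, 3974 genes were higher and 2698 lower. Scaled instead by library totals, an alternative chosen after the data were seen, 802 were higher and 6892 lower, because every log2 fold moved by about -0.71. Scaling by totals without mitochondrial genes gave 1151 and 6253, with a shift of -0.54. Directions below are those of the deposited scaling. A common shift leaves the difference of medians between a list and all other genes as it is, though some camera p-values moved. Fry tests each list alone, so its directions can follow the scaling, and it was not rerun under totals. Under library totals Banf1, Nfkb2, Cxcl1, Ctsd, Srf, Col3a1, Gsn, Cdh5, Tie1 and Abcc9 were no longer called.

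Of 30 gene lists, 26 had enough tested members, and by camera with its preset correlation 12 stood higher and 3 lower than other genes. None of these 15 calls held with an estimated correlation between members (lowest adjusted p = 0.33), while fry, which tests each list alone, found 18 lists moving on balance in a single direction. Camera sets a list against other genes of any level, and folds differed with level. The median log2 fold was -0.29 in the third octile by level and 0.41 in the highest. Of the lists, only nuclear oxidative phosphorylation was also set against genes of the same level. How far level accounts for the other list calls was not tested. Members named as exceptions to a list's direction were chosen after their values were seen.

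**Figure D2:**
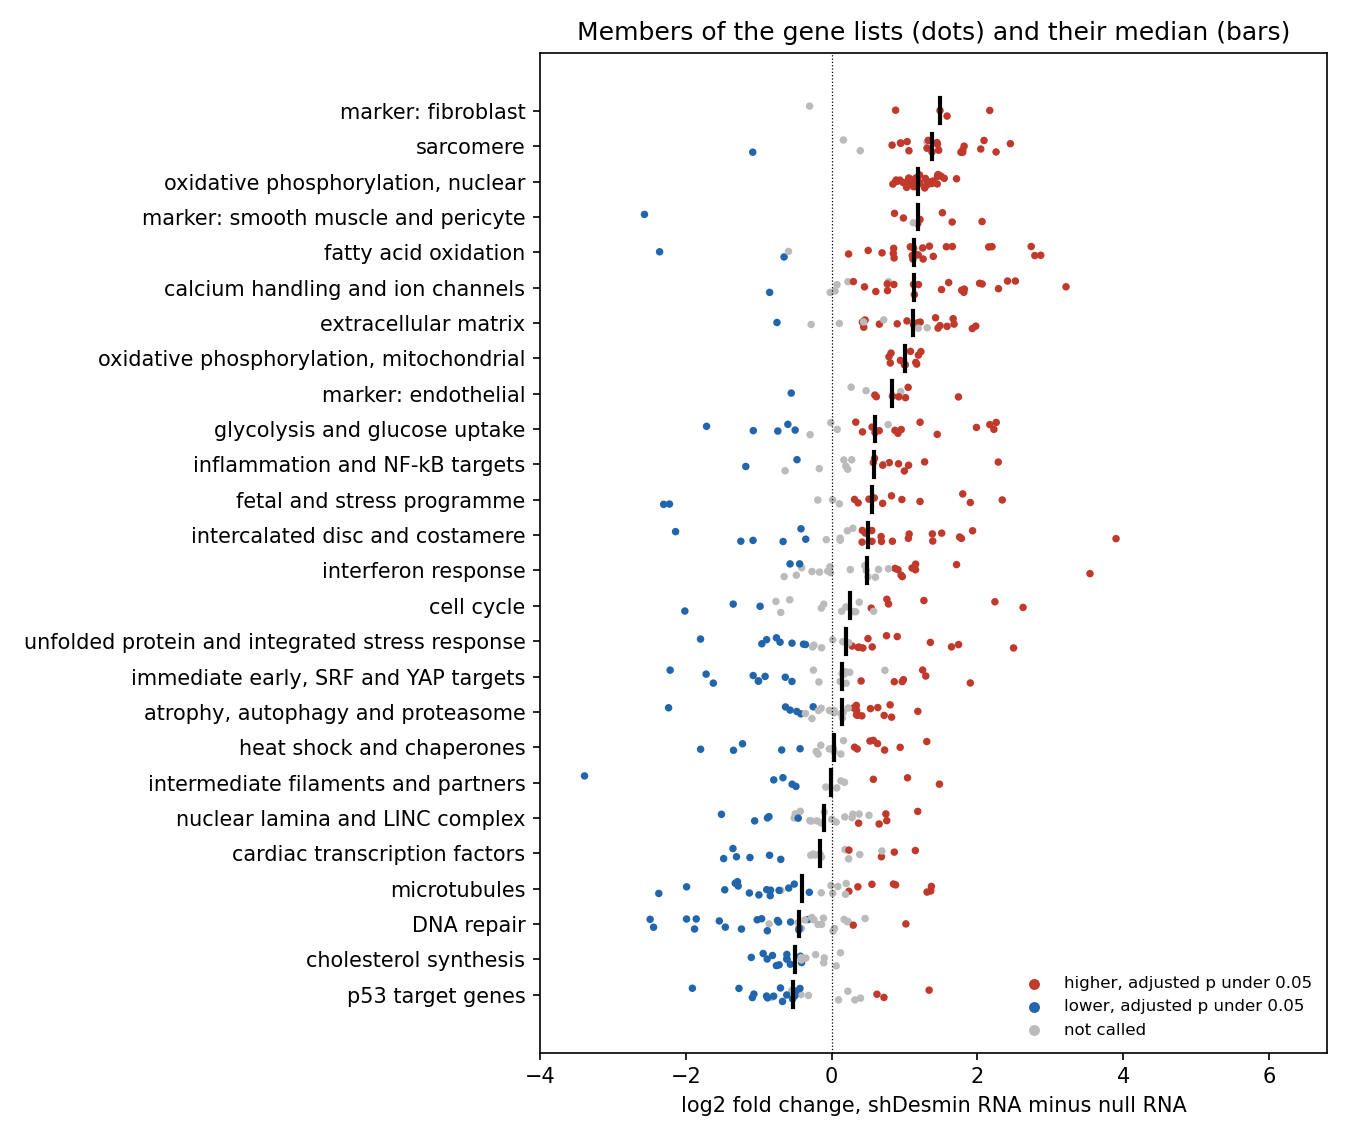
Log2 fold change (horizontal axis, shDesmin RNA minus null RNA, deposited scaling) of each tested member (dots) of 26 gene lists, with the list median as a black bar. All 34 nuclear oxidative phosphorylation members lie between 0.84 and 1.71, whereas intermediate filament members run from -3.39 for Des to 1.48 for Synm.

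Most transcripts of the sarcomere and of calcium handling were higher, and those of cell junctions were mixed. Of 23 tested sarcomere genes 19 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 fold of 1.38, or 0.52 under quantile normalization. The M-line gene Myom2 rose from 8.69 ± 0.08 to 11.14 ± 0.03 log2 CPM (SD, n = 3, 5.47-fold, adjusted p = 1.5e-08), Myom1 3.48-fold and the Z-disc gene Ldb3 3.42-fold. The list stood above other genes by camera (adjusted p = 8.6e-10, and adjusted p = 0.38 with an estimated correlation). Genes of calcium handling and ion channels moved likewise, with 20 of 26 higher and 1 lower, the potassium channel gene Kcnd3 (the same counts adjusted over the list alone). In this list Pln rose 9.28-fold and Hrc, which encodes a calcium-binding protein of the sarcoplasmic reticulum, 5.32-fold (camera adjusted p = 3.6e-08, and adjusted p = 0.33 with an estimated correlation). Of 28 genes of the intercalated disc and costamere, the sites that couple myocytes to each other and sarcomeres to the membrane, 17 rose and 6 fell (18 and 6 adjusted over the list alone). The desmosomal Dsp rose 2.85-fold and N-cadherin Cdh2 2.62-fold, whereas Xirp1, an actin-binding protein gene of the disc, fell 4.41-fold. That list's median log2 fold was 0.51, and -0.21 under library totals (camera adjusted p = 0.0083, and adjusted p = 0.57 with an estimated correlation), and quantile normalization ended its call (adjusted p = 0.58).

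Transcripts of mitochondrial energy production rose together. All 34 tested nuclear genes of oxidative phosphorylation were higher (34 adjusted over the list alone), with a median log2 fold of 1.19, or 0.44 under quantile normalization. The complex III gene Uqcrc2 rose from 9.37 ± 0.06 to 10.83 ± 0.08 log2 CPM (SD, n = 3, 2.75-fold), and the complex II genes Sdhc and Sdhd rose 2.59-fold and 2.92-fold (camera adjusted p = 5.4e-16, and adjusted p = 0.46 with an estimated correlation). All 11 tested mitochondrially encoded genes were also higher (11 adjusted over the list alone, median 1.01, camera adjusted p = 0.00044, and adjusted p = 0.51 with an estimated correlation), among them Mt-nd4l at 2.24-fold and Mt-atp8 at 2.28-fold. Under quantile normalization, which ties the top ranks of all libraries, that median was 0.00 (camera adjusted p = 0.71), Mt-atp8 was no longer called and Mt-nd5, 2.34-fold higher here, stood at -0.04. Mitochondrial genes took 24.7, 30.6 and 34.5% of reads in the null libraries and 35.0, 39.1 and 39.0% in the shDesmin libraries. Of 26 fatty acid oxidation genes 23 rose, and Ucp3 and Cpt1a fell (23 and 3 adjusted over the list alone, median 1.13, or 0.48 under quantile normalization), with Lpl 6.90-fold, Fabp3 7.30-fold and the electron transfer gene Etfdh 2.98-fold higher (camera adjusted p = 3.6e-10, and adjusted p = 0.33 with an estimated correlation). Glycolysis and glucose uptake was mixed, with 14 of 23 higher and 5 lower (the same adjusted over the list alone) and a median of 0.60, or 0.19 under quantile normalization and -0.12 under library totals. The muscle forms Pfkm (4.50-fold) and Eno3 (4.78-fold) and the insulin-responsive glucose transporter gene Slc2a4 (3.96-fold) rose, while Pfkfb2, Pfkp, Slc2a1, Hk2 and Pfkl fell (camera adjusted p = 0.0053, adjusted p = 0.46 with an estimated correlation and 0.19 under quantile normalization).

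Cytoskeletal and nuclear envelope transcripts went both ways, though all tested tubulin genes except Tuba8 fell. Among 12 intermediate filament genes and partners, Synm, which encodes the desmin partner synemin, rose 2.79-fold, and Vim and Cryab rose too, whereas Des, the cytolinker gene Plec (1.73-fold), Sync, Nes and Macf1 fell (3 and 5 adjusted over the list alone). The list did not stand apart by camera (adjusted p = 0.66), and its median took either sign, from -0.72 under library totals to 0.18 with median centring. Its mean of -0.21 and its fry call (adjusted p = 0.017, lower) rest on Des, since without Des, a test chosen after the data were seen, the mean was 0.08 and the fry adjusted p = 0.65. Of 30 microtubule genes 15 fell and 8 rose (the same adjusted over the list alone), with a median of -0.41. The tubulin genes Tubb4b (8.73 ± 0.13 to 6.36 ± 0.18 log2 CPM, SD, n = 3, 5.17-fold, adjusted p = 8.6e-08) and Tubb6 (3.97-fold) fell. So did the tubulin genes Tubb2a, Tubb3, Tubb5, Tuba1a, Tuba1b, Tuba4a and Tubg1, while Tuba8 rose by 0.36 on the log2 scale. Tubulin genes were set apart after their values were seen, without a test of their own. The plus-end binding protein gene Mapre2 rose 2.57-fold (for the whole list, camera adjusted p = 0.13, and fry adjusted p = 0.0023). Of 25 genes of the nuclear lamina and the LINC complex, which tethers the cytoskeleton to the nucleus, 5 rose and 5 fell (the same adjusted over the list alone). Lmna, which encodes the A-type lamins, fell 1.84-fold and Tmem43 1.81-fold, as did Tor1a, Lemd3 and Prr14. Banf1 rose 1.68-fold, as did Lbr, Tpr, Sun2 and Hdac3, and the list did not stand apart (camera adjusted p = 0.98).

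Targets of p53, the DNA damage response factor, and DNA repair genes were lower on balance. Of 25 p53 targets 14 fell and 3 rose, the latter Tp53inp1, Gadd45a and Perp (15 and 3 adjusted over the list alone). Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 9.23 ± 0.04 to 7.96 ± 0.15 log2 CPM (SD, n = 3, 2.41-fold, adjusted p = 1.3e-06), Aen 2.12-fold and Phlda3 2.09-fold. The camera adjusted p of 0.042 became 0.062 without null RNA replicate 1, 0.063 without shDesmin RNA replicate 2, 0.065 without shDesmin RNA replicate 3 0.054 under a stricter filter, 0.068 under library totals and 0.059 under totals without mitochondrial genes (adjusted p = 0.51 with an estimated correlation). Of 34 DNA repair genes 17 fell and 2 rose (the same adjusted over the list alone). The end-joining ligase gene Lig4 fell 5.43-fold and the mismatch repair gene Msh6 2.91-fold, while Parp1 rose 2.03-fold and Chek1 by 0.30 on the log2 scale. Its camera adjusted p of 0.019 became 0.065 under the stricter filter and 0.058 under quantile normalization (adjusted p = 0.33 with an estimated correlation). Among 20 cell cycle genes 6 rose and 3 fell (the same adjusted over the list alone), with Ccne2 6.17-fold higher and Ccnd1 2.55-fold, Aurka 4.04-fold and Cdc20 lower (camera adjusted p = 0.41).

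Each stress-related list held genes that rose and genes that fell, and cholesterol synthesis genes fell or were not called. In the fetal and stress programme, genes re-expressed in failing hearts, 11 of 16 rose and 2 fell, among them Gdf15 (4.93-fold, the same counts adjusted over the list alone). Myh7, the slow myosin heavy chain gene, rose 3.48-fold. Myh6, the other cardiac myosin heavy chain gene, of the sarcomere list, rose 4.13-fold, so Myh7 did not rise relative to Myh6. The list's median was 0.55, but -0.16 under library totals and -0.15 under quantile normalization (camera adjusted p = 0.019, adjusted p = 0.38 with an estimated correlation and 0.58 under quantile normalization). Of 25 immediate early, SRF and YAP target genes 7 rose, with Ankrd1 3.74-fold and Myl9 2.45-fold, and 9 fell, with Ajuba 4.64-fold (the same adjusted over the list alone, camera adjusted p = 0.98). Of 26 unfolded protein and integrated stress response genes 12 rose and 8 fell (13 and 9 adjusted over the list alone), with Dnajb9 3.34-fold, Pdia4 3.13-fold and Atf4 2.56-fold higher (camera adjusted p = 0.30, and fry adjusted p = 0.020, higher). That list's median was 0.19, or -0.52 under library totals. Heat shock and chaperone genes divided into 8 higher and 5 lower of 21 (the same adjusted over the list alone), with Hspb7 2.47-fold higher and Hspb8 2.33-fold and Hspb3 3.47-fold lower, beside Dnajb1, Hsph1 and Dnaja1 (camera adjusted p = 0.65, and 0.030 in the lower direction under quantile normalization). Of 30 atrophy, autophagy and proteasome genes 12 rose and 6 fell (the same adjusted over the list alone). The muscle ubiquitin ligase gene Trim63 fell 4.71-fold, while Map1lc3a rose 2.27-fold and Ctsd 1.65-fold (camera adjusted p = 0.23, and fry adjusted p = 0.018, higher). The median of this list was 0.14, or -0.57 under library totals. No member of the cholesterol synthesis list rose and 12 of 20 fell (the same adjusted over the list alone), among them Msmo1 (2.15-fold), Idi1 (1.92-fold) and Fdft1 (1.69-fold), and the list stood lower than other genes (camera adjusted p = 0.0053, and adjusted p = 0.51 with an estimated correlation).

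Innate immune transcripts were higher in part. Of 26 interferon response genes 9 rose, with Cxcl10 11.7-fold and Cxcl11 2.22-fold higher, and Irf1 and Stat2 fell (8 and 2 adjusted over the list alone). The list missed the threshold (camera adjusted p = 0.055), passed it without null RNA replicate 2 (0.027), without shDesmin RNA replicate 1 (0.043), under quantile normalization (0.015), under library totals with or without mitochondrial genes (0.013 and 0.017) and by fry (0.0097), and missed it with an estimated correlation (adjusted p = 0.51). Its median was 0.49, or -0.22 under library totals. Of 18 inflammation and NF-kB targets 9 rose, among them Ccl20 4.88-fold and Cxcl1 2.00-fold, and Bcl3 and Birc3 fell (the same adjusted over the list alone). Nfkb2, 1.63-fold higher here, stood at -0.01 on the log2 scale under library totals, where the list's median of 0.58 became -0.13. That list's camera adjusted p of 0.045 became 0.092 without null RNA replicate 1, 0.052 without null RNA replicate 3 and 0.083 without shDesmin RNA replicate 3 (adjusted p = 0.51 with an estimated correlation). It was also lost under the stricter filter (0.091), median centring (0.054), quantile normalization (0.058) and scaling by totals (0.061 and 0.050).

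Among 19 cardiac transcription factor genes 6 fell and 4 rose (the same adjusted over the list alone, camera adjusted p = 0.66). Gata4 fell 2.79-fold and Nkx2-5 2.56-fold, both core regulators of cardiac identity, while Srf rose 1.81-fold, as did Ppargc1a, Esrrg and Esrra, regulators of mitochondrial genes.

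Extracellular matrix genes and markers of other cardiac cell types were also higher. Of 25 matrix genes 17 rose and Lamb1 fell (18 and 1 adjusted over the list alone), with Sparc 2.32-fold, Lama2 2.05-fold and Col5a1 3.20-fold higher (median 1.12, camera adjusted p = 0.00088, and adjusted p = 0.51 with an estimated correlation). Of 5 tested fibroblast markers 4 rose, with Dcn 4.49-fold, Col3a1 2.80-fold and Gsn 1.84-fold higher (4 adjusted over the list alone, camera adjusted p = 0.15, 0.018 under library totals, and adjusted p = 0.51 with an estimated correlation at the deposited scaling). Dcn and Col3a1 were low and variable in null RNA, at 0.56 ± 1.21 and 1.565 ± 0.63 log2 CPM (SD, n = 3), against 4.01 ± 0.43 for Gsn. Of 11 endothelial markers 7 rose, with Cdh5 2.07-fold, Tie1 1.89-fold and Flt1 3.34-fold higher, and Kdr fell (the same adjusted over the list alone, camera adjusted p = 0.044, and adjusted p = 0.57 with an estimated correlation). Flt1 was likewise low in null RNA (-0.05 ± 0.71 log2 CPM, SD, n = 3), against 5.87 ± 0.38 for Cdh5 and 6.08 ± 0.43 for Tie1. Of 9 smooth muscle and pericyte markers 7 rose, with Acta2 2.32-fold and Abcc9 1.82-fold higher, and Cspg4 fell 5.93-fold (8 and 1 adjusted over the list alone, camera adjusted p = 0.046, and adjusted p = 0.57 with an estimated correlation). Acta2 also stands in the fetal and stress list. The endothelial call was lost without null RNA replicate 1 (0.10), null RNA replicate 3 (0.081) or shDesmin RNA replicate 3 (0.084), and the smooth muscle call without the same libraries (0.071, 0.081 and 0.095), as both were with median centring (0.060 and 0.087), under the stricter filter (0.096 and 0.091) and by fry (0.099 and 0.093). Quantile normalization also ended the smooth muscle call (camera adjusted p = 0.058). In 3 lists only 2 members each were tested. Ncam1 and Tubb3 of the neuronal list fell 2.49-fold and 1.79-fold, and Cnp of the Schwann and mesothelial list 2.95-fold. The macrophage gene Csf1r fell 8.97-fold, and Cd68 was not called at 0.55 ± 0.44 and 0.74 ± 0.47 log2 CPM (SD, n = 3). The Tubb3 call was lost without null RNA replicate 2 (adjusted p = 0.071). No red blood cell marker passed the filter.

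LADs are stretches of chromatin held at the nuclear lamina, and the control list covered a large part of the rat genome but few expressed genes. It held 1883 domains of 1252 megabases in total, with a median length of 309 kilobases. The longest, 11.8 megabases, ran from 70904401 to 82742399 on rn6 chromosome 15. Domains of at least 1 megabase, 367 in number, made up 63.1% of the covered length. Over chromosomes 1 to 20 and X, 43.4% of the sequence spanned by genes and domains lay in LADs. The share ran from 11.5% on chromosome 12 and 22.7% on chromosome 10 to 54.4% on chromosome 2 and 64.7% on chromosome X. Only 436 of 11000 tested genes on these chromosomes, 3.96%, had at least 50% of their length in a LAD, with 14.1% on chromosome X and 0.41% on chromosome 10. Because the authors pooled 3 replicates into this single list and defined no LADs in shDesmin cells, the domains have no replicate error here and no comparison of LADs between groups was made.

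Genes inside the LADs of scrambled shRNA cells were expressed at lower levels in null RNA. No RNA library came from scrambled cells, so domains and levels were measured in differently treated controls. The median level of LAD genes in null RNA was 2.35 log2 CPM against 4.01 for the 10564 genes outside, a difference of -1.66. Rotating the LADs along their chromosomes 10000 times gave p = 0.0001 (two-sided permutation), the smallest value such rotations can give. That p carries little weight, since rotated domains held a median of 4427 genes and the test called 46 of 100 simulated sets of folds without an effect. Shifting the LAD genes in gene order, an alternative chosen after the data were seen, also gave p = 0.0001 (two-sided permutation).

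Genes in LADs fell less often than genes elsewhere when desmin was depleted. In LADs 78 of 436 genes (17.9%) were lower in shDesmin RNA, against 3381 of 10564 outside (32.0%, Fisher's exact test, two-sided, odds ratio 0.46, p = 9.5e-11). The shares of higher genes were 27.8% and 27.3% (121 and 2884 genes, odds ratio 1.02, Fisher's exact test, p = 0.83). The median log2 fold was 0.10 in LADs and -0.05 outside, a difference of 0.15. Among genes in LADs with a symbol and a mean of at least 3 log2 CPM, the 5 called genes with the largest change all rose. They were Tecrl (12.2-fold, chromosome 14, 26662965 to 26737657), the enkephalin precursor gene Penk (2.50 ± 0.33 to 4.78 ± 0.24 log2 CPM, SD, n = 3, 4.85-fold, chromosome 5, 17056419 to 17061837), Igsf1 (4.38-fold, chromosome X, 136792643 to 136807885), Dnajb9 (3.34-fold, chromosome 6, 64165914 to 64170122) and the methylmalonyl-CoA mutase gene Mut (3.00-fold, chromosome 9, 23323936 to 23352668). Against 10000 draws of outside genes matched on mean log2 CPM, where a median of 32.6% were lower and 21.1% higher, the LAD genes had fewer lower (p = 0.0001) and more higher calls (p = 0.0004, permutation). For the difference of medians, rotation of the LADs gave a permutation p = 0.0001, but rotated domains held a median of 4427 genes and this test called 46 of 100 simulated sets without any effect. Shifting the LAD genes in gene order, which called 3 of 100 such sets, gave p = 0.0066, and camera on the LAD genes missed the threshold (p = 0.093, and p = 0.18 with an estimated correlation).

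**Figure D3:**
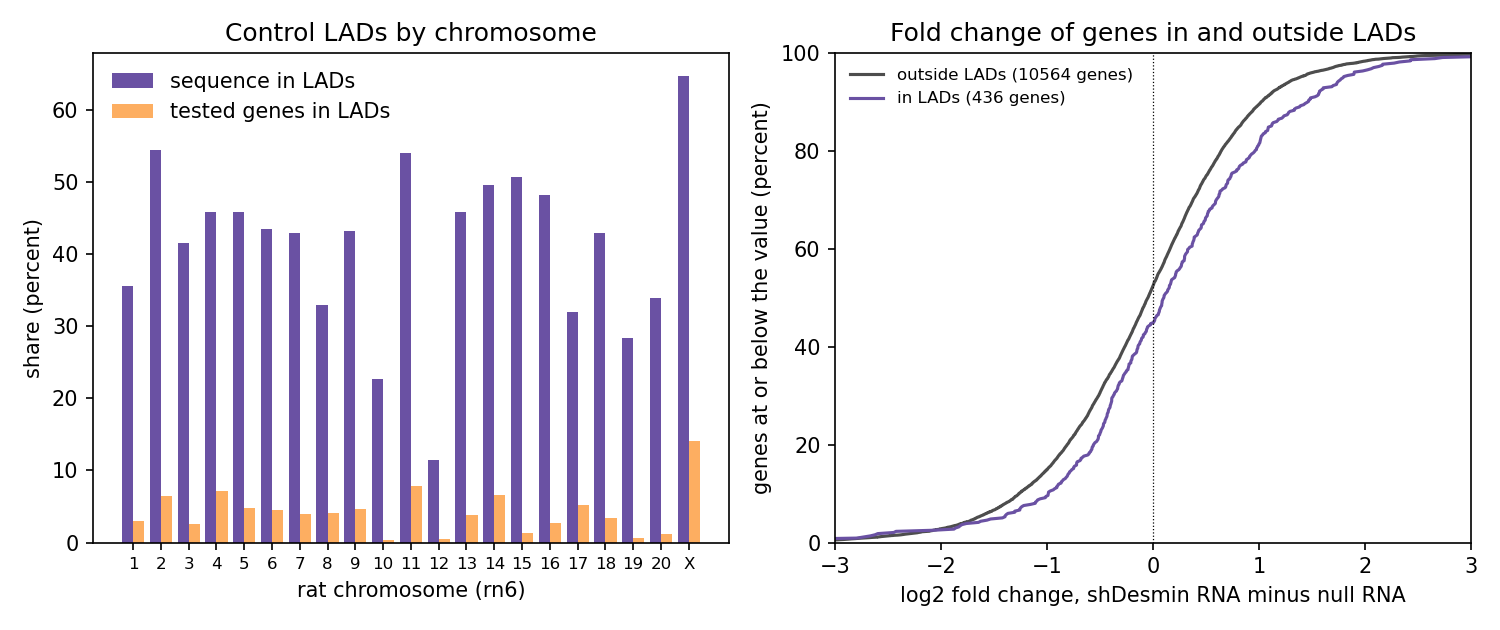
Left, the percent of each chromosome's sequence (purple) and of its tested genes (orange) in control LADs, from 11.5% of sequence on chromosome 12 to 64.7% on X. Right, the percent of genes at or below each log2 fold change (shDesmin RNA minus null RNA) for 436 genes in LADs and 10564 outside, with medians of 0.10 and -0.05.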

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

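Chosen after the data were seen were both scalings by totals, voom, the shift in gene order and the filament list without Des. Des fell in every setting, by 3.21 (median centring) to 4.31 (quantile normalization) on the log2 scale. Except under scaling by totals, counts of changed genes stayed within 1.5 times the reported ones. They ran from 5657 to 6611 when 1 library was left out, and were 4888 at adjusted p under 0.01, 6470 with voom and 6507 in the authors' deposited table. Scaling by library totals gave 802 higher and 6892 lower genes, 313 and 4232 of them at least 2-fold. Totals without mitochondrial genes gave 1151 and 6253, 420 and 3504 of them at least 2-fold. The construction shows the cause, a shift of -0.71 or -0.54 for every gene. For the lists, estimated correlations left 0 higher and 0 lower, fry gave 5 lower, the stricter filter (fewer genes) 1 lower and quantile normalization 7 higher. Under quantile normalization the fetal and stress list moved to -0.16 and the heat shock list to -0.41 relative to other genes, and Mt-nd5 to -0.04, while under library totals Nfkb2 moved to -0.01. The causes were not tested. Without Des the filament list stood at 0.11 relative to other genes and was not called by camera. For named genes and lists, a verdict is the same where a call was kept or a result stayed without a call. Leaving out 1 library gave 601 same and 5 weaker verdicts for genes, and 142 same, 12 weaker and 2 stronger for lists. The other planned settings gave 1005 same, 1 weaker and 1 reversed for genes, and 194 same, 31 weaker, 6 stronger and 2 reversed for lists. The added settings gave 286 same, 16 weaker and 1 reversed for genes, and 45 same, 4 weaker and 4 stronger for lists.

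The replicate block gave 6583 changed genes, with 12 lists higher and 3 lower, and changed no call of a list or a named gene.

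In LADs the level difference ran from -1.81 to -1.12 and the fold difference from 0.14 to 0.25 over the alternatives used for LADs. With 1 library left out the fold difference was 0.14 to 0.17, and no sign changed. The pseudocounts, the variance model, library weights, voom and the authors' deposited values were not used for LADs. Rotation p values stayed at their smallest, which says little because that test calls too often. By the shift in gene order, rerun under each alternative used for LADs except matching, p for the fold difference ran from 0.0003 (quantile normalization, permutation) to 0.032 (the stricter filter). Camera on the LAD genes missed the threshold, and the shares of called genes were rerun only for other definitions of a gene in a LAD. Count tests on the recovered reads and placing genes by transcription start (no strand) were not run.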

Other observations

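The tests below were chosen after the results were seen, the splits of the libraries included, except the matching of LAD genes on level, which was planned. Among genes outside the lists, 3 neighbouring lincRNA features of the RNA table rose together. Rn60_1_2212.3 (rn6 chromosome 1, 221151827 to 221153278), Rn60_1_2212.2 (221154561 to 221156910) and Rn60_1_2212.4 (221158098 to 221158792) were 9.14-fold, 9.14-fold and 9.74-fold higher in shDesmin RNA. The most abundant, Rn60_1_2212.2, went from 7.76 ± 0.24 to 10.95 ± 0.05 log2 CPM (SD, n = 3, limma adjusted p = 1.5e-08). The files give these features no gene name, and features this close can share a transcript.

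Mitochondrial tRNA genes rose like the mitochondrial protein-coding genes, all 14 of those tested, with a median log2 fold of 1.43. AABR07060522.2, a misc_RNA feature of chromosome 4 (77459794 to 77459895), had 2 reads in all null libraries and 251 in the shDesmin libraries, a ratio of 206 (95% exact binomial interval 56.5 to 1712, counting error only). St8sia2 had 0 reads in the null libraries and 15 to 24 in each shDesmin library (2.64 ± 0.60 CPM, SD, n = 3), at least 9.74-fold higher than the limit of 3 reads per library.

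The rise of oxidative phosphorylation transcripts is a pattern that a technical difference could give. Scaling between libraries is argued against as the whole cause, since under library totals the nuclear list still had a median of 0.476 and its lowest member stood at 0.13. Fewer other cells in the shDesmin cultures would lower their markers, but the lowest median of the fibroblast, endothelial and smooth muscle lists was 0.834. That lowest median was 0.48 without null RNA replicate 3, 0.29 under totals without mitochondrial genes and 0.12 under library totals. In shDesmin RNA Cdh5 stood at 6.92 and Acta2 at 8.37 log2 CPM. However, 6 genes of these lists also stand in other lists, and Csf1r fell. Acta2 is one of the 6, also placed in the fetal and stress programme, so its level need not come from other cells. Median folds were above 0 only in the most abundant genes, -0.18 in the lowest octile by level, -0.29 in the third and 0.41 in the highest. The highest median of 10000 lists matched on level was 1.14 (median 0.56), under the observed 1.19. Those draws treat genes as independent, while members of the nuclear list had an estimated correlation of 0.66. The draws therefore do not show how far a correlated list could stray from 0.56. A share of the level in this rise stays open. Also open, and untested, are a difference between cell preparations or library batches that follows the groups, the effect of an shRNA as such, and desmin depletion itself.

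A low level or a longer gene span could give the smaller share of lower genes in LADs. Against outside genes matched on level the difference of median log2 folds was 0.252 (permutation p = 0.0001), and matched on level and gene span it was 0.2 (p = 0.0005), against 0.15 without matching. Of outside genes matched on level, 32.6% were lower, against 17.9% in LADs, so level and span are argued against as the cause, in draws that treat genes as independent. In 1 of 10 splits of the 6 libraries, the real one, the difference was as large, 0.151 against at most 0.108 in size in the others, too few splits for a share under 0.05. A difference between cell preparations or library batches that follows the groups, and the effect of an shRNA as such, stay open and untested here too. A loss of lamina contact on desmin depletion is likewise an untested hypothesis, since the LAD list covers control cells only.

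The same 10 splits bear on the counts. The real split gave 6495 changed genes and 2750 changed at least 2-fold, against 0 and 0 in each of the others, so 1 split in 10 reached each count. Every other split mixes libraries of both groups, which puts the group difference into the spread within its sides. Few calls could be had there, so the counts of 0 do not show how many genes would be called without a group difference. For gene lists by camera with its preset correlation, the real split gave 15 and another split 16, so 2 of the 10 were as large. With 10 splits no share under 0.05 can be had.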
